A study of Prunus persica with 9 samples.

How the data were processed

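Cy3-labelled target was made from 250 ng of fruit RNA per sample and hybridised to one-colour arrays, per the labels' protocols, and scans were read with Agilent Feature Extraction 9.5, per the submitters' processing notes. The deposited scanner files give an intensity for each spot, background-subtracted and detrended within the array by that software per the file headers, and not scaled between arrays. The authors also deposited a value table of linear ratios, which its values show to be relative to the median of each row. The medians of its columns lie between 0.865 and 1.20, and its scaling between arrays is not given in the sources used here. The table has 43754 rows. Under its own row names it correlated with the scanner values at an r between 0.00393 and 0.0527 per array, across probes well above background on all 9 arrays. Its rows were therefore counted without names, as an alternative.

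Samples were grouped from the labels. Control spots were left out, as were spots with an outlier flag, between 3 and 238 per array, and a probe with such a spot on an array of a fit was not tested in it. The rule on flagged spots is not in the plan written before the data were examined, so counts with those spots kept are given among the alternatives. No probe was saturated. Values were log2 of the processed intensity minus the 75th percentile of the array. Probes well above background on at least 2 of 9 arrays were kept, 27637 of 43803.

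Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The propylene fit used the 4 stony hard arrays with cultivar as a block, which is also the slide. The trend was a slope on days over 4 Akatsuki arrays. Akatsuki at commercial maturity was compared in a 5-array fit of group means. A size rule counted probes changed at least 2-fold in both cultivars. Trend probes were set against 10000 random sets drawn within 20 bins of mean signal. Files were read with the data.table package (1.17.8) and plots drawn with matplotlib 3.10.9. All arrays were scanned as 3 slides, with the dated Akatsuki arrays on slide 1, Odoroki on slide 2, and Manami and Akatsuki at commercial maturity on slide 3.

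Only 15 probes, of 12 genes, carry a gene name in the files, and the reference table matched no other identifier. The planned pathway lists are patterns on annotation text, which is empty here, so 0 lists had a member and no set test was run. All named genes are reported, each through its brightest probe, and up to 2 unnamed probes per direction are given in the trend and propylene comparisons. The rule was the largest change past the threshold, or, where none passed, the largest among probes well above background on all arrays of the fit. The adjustment over gene-named genes alone was added after the names were seen. Auxin genes carry no name in these files and are not analysed here.

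The fits were tested on simulated arrays of 27637 probes with 200 changed. With a low spread (SD 0.2), the propylene fit recovered 89% of probes changed by 2 log2 and 99% of those changed by 4, with 25 false calls. The fit for commercial maturity, simulated for the contrast with air only, recovered 70% and 98% with 8 false calls. The trend fit recovered 97% of slopes of 0.3 per day and 3% of slopes of 0.1, with 5. With the spread of the real fits, the propylene and maturity fits recovered 0% of either size, and the trend fit 74% of slopes of 0.3 and 0% of slopes of 0.1.

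Alternatives were quantile and median scaling, normexp background correction with an offset of 50, the authors' ratios, other filters on dim probes, an intensity trend in eBayes, other models and samples, and other fold sizes. Chosen after seeing the data were keeping flagged spots, removing the local median over the nearest 50 bright spots, a percentile over probes well above background on all 9 arrays, slide as a block, and a filter on the 4 stony hard arrays.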

Results

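Peach (Prunus persica) fruit RNA was measured on 9 one-colour oligonucleotide arrays, 1 per sample. Akatsuki, a melting-flesh cultivar that softens as it ripens, was sampled at 92, 98, 104 and 106 days after full bloom. Another Akatsuki sample was taken at commercial maturity, with no day given. Odoroki and Manami, cultivars of the stony hard type, were harvested at commercial maturity and held for 3 days in air or in propylene at 5000 µl per l, an analogue of ethylene. Each stony hard cultivar gave 1 air and 1 propylene sample, so the cultivars served as the 2 replicates of a treatment, while each Akatsuki stage had 1 array and no replicate. The p-values of the propylene and commercial maturity comparisons therefore measure the spread between these few samples. Those of the trend measure the departure of single arrays from a straight line over days, with no replicate of any day. The number of arrays limits the precision of both. Of 43803 probes, between 57.2% and 62.2% read well above background on 7 arrays, against 48.3% for Akatsuki at commercial maturity and 26.7% for Manami in air. The 75th percentile of the signal was 56.1 for Manami in air and 196 for Akatsuki at commercial maturity, and lay between 973 and 1577 on the other arrays. Levels below are log2 signals relative to the 75th percentile of the array, and levels of different probes are not comparable.

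The 4 dated Akatsuki samples address which transcripts change as a melting fruit ripens on the tree. PpACS1, an ACC synthase that makes the precursor of ethylene, rose by 0.86 log2 per day (SE 0.08, limma adjusted p = 0.0290 over all probes). It was not well above background at 92 days and read -1.67 at 98, 1.53 at 104 and 3.59 at 106 days, which is at least 1370-fold higher at 106 than at 92 days. PpEndoPG, an endopolygalacturonase that cuts pectin in the cell wall, was not well above background at 92 and 98 days and read 2.20 at 104 and 7.64 at 106 days, at least 22705-fold higher at the last day than at the first. Its slope of 1.13 log2 per day (SE 0.17) missed the threshold over all probes in limma (adjusted p = 0.0548). Bounds here set the brighter signal against the lowest signal well above background on the dim array, or the dim probe's own where higher.

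The other ethylene genes moved less. PpACO1, an ACC oxidase that carries out the last step of ethylene synthesis, read 5.85 at 92 and 7.70 at 106 days, with a slope of 0.13 per day (SE 0.02, limma adjusted p = 0.0611). The ethylene receptor gene PpERS1 went from 1.65 to 3.06 (limma adjusted p = 0.110), and the receptor gene PpETR1 from 1.68 to 1.69 (limma adjusted p = 0.904). PpSorTp read 5.09 at 92 and 3.27 at 106 days, a slope of -0.13 per day (SE 0.02, limma adjusted p = 0.0513). The expansin genes PpExp1, PpExp2 and PpExp3, whose products loosen cell walls, had slopes of 0.05, -0.02 and 0.04 per day, and none passed limma. PpHexTp had a slope of 0.05 (limma adjusted p = 0.171). Of the 10 gene-named genes tested, 1 passed over all probes and 5 passed when adjusted over those 10 alone, namely PpACS1, PpEndoPG, PpACO1, PpERS1 and PpSorTp. PpACS2 was not well above background on any array, and PpACS3 only at 104 days.

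Over all 27384 probes tested, limma called 359 rising and 351 falling probes. Among probes with no gene name, Prunus_v4_Contig137 (probe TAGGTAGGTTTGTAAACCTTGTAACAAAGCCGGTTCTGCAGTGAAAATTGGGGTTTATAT) and R_Prunus_v4_Contig427 rose, from not well above background at 92 days to levels at least 9875-fold and 4731-fold higher at 106 days. R_Prunus_v4_Contig791 fell to not well above background at 106 days, at least 300.2-fold lower than at 92 days. Prunus_v4_Contig2141, well above background on all 4 arrays, had a slope of -0.54 per day (SE 0.05). The fitted slopes of the first 3, by which they were chosen, and those of PpACS1 and PpEndoPG include signals not well above background. The files do not pair these identifiers with genes. Without the 92-day or the 98-day array limma called 0 probes, without the 106-day array 167, and 0 when 104 and 106 days were set against 92 and 98. All 4 arrays lay on 1 slide.

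**Figure D1:**
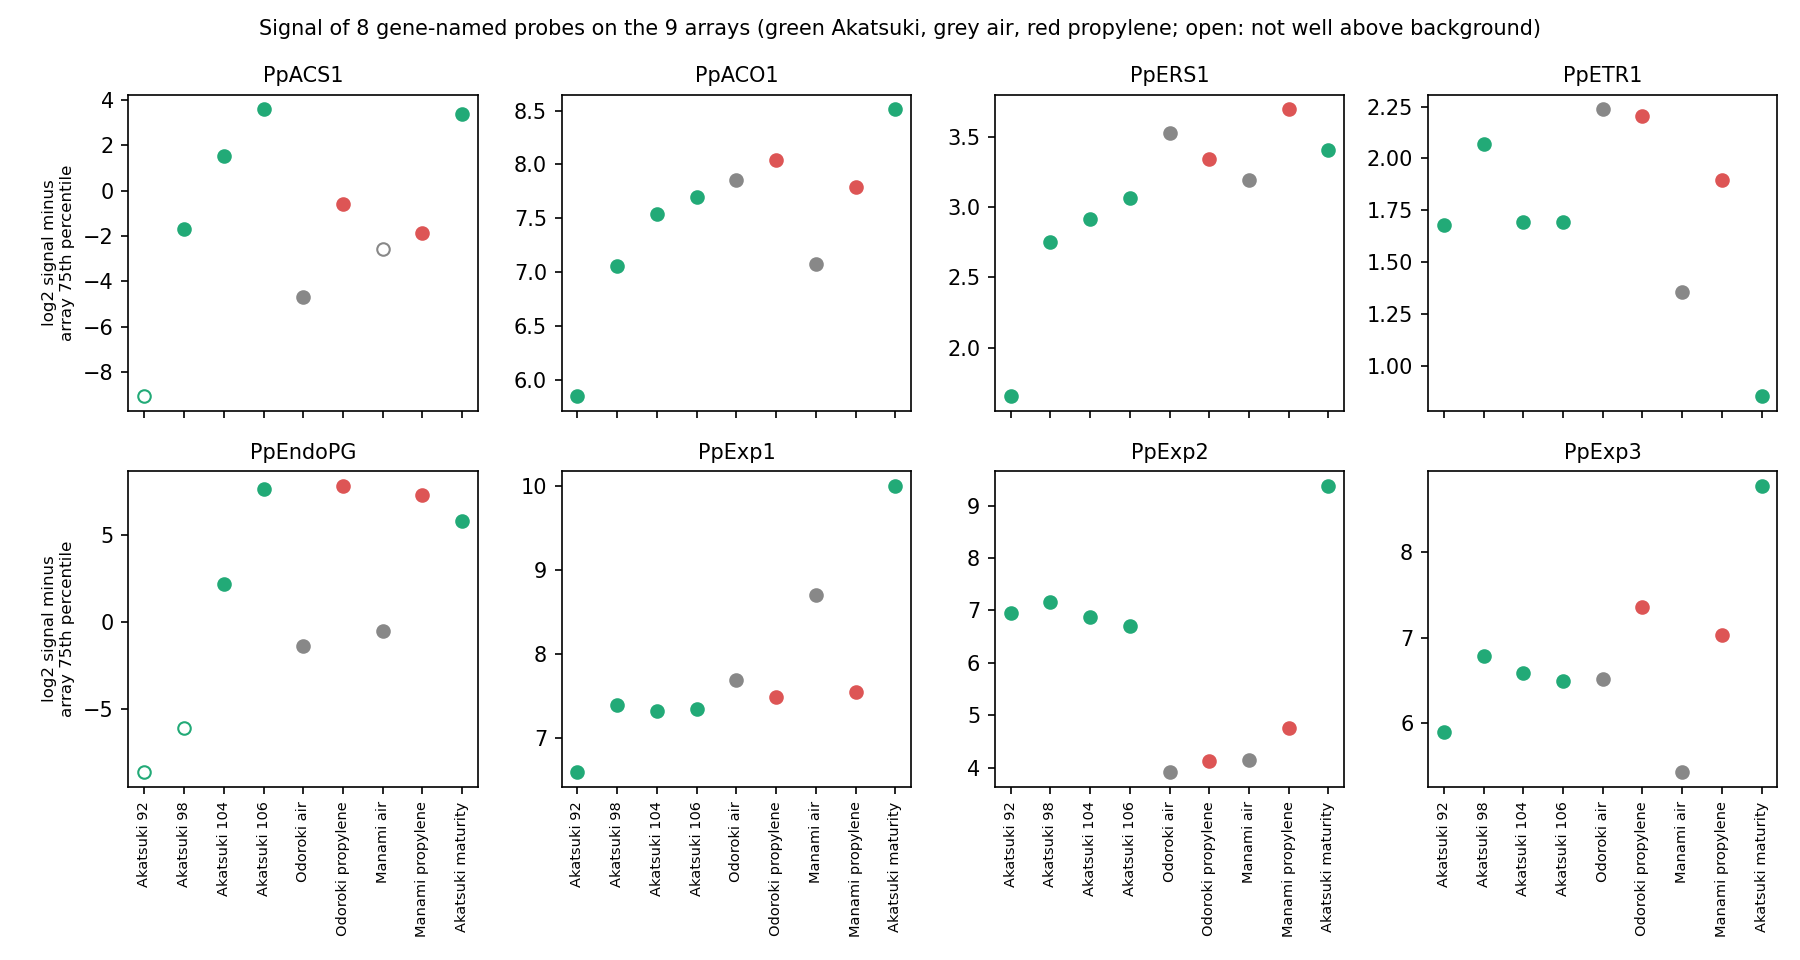
Log2 signal minus the 75th percentile of the array (vertical axis, a different range in each panel) for 8 gene-named probes on the 9 arrays (horizontal axis), each point being 1 array (green Akatsuki, grey stony hard in air, red stony hard in propylene); open points were not well above background. PpEndoPG read 7.85 and 7.33 after propylene, near its 7.64 in Akatsuki at 106 days, while PpACS1 read -0.57 and -1.86 after propylene against 3.59 in Akatsuki at 106 days.

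Propylene and air were compared within each stony hard cultivar, to show which transcripts answer an ethylene analogue in fruit of this type. PpEndoPG was higher after propylene in both cultivars, by 9.20 log2 in Odoroki and 7.85 in Manami, a mean of 8.52 (SE 0.75, n = 2 cultivars). The limma adjusted p was 0.791 over all probes and 0.00715 over the 10 gene-named genes. PpACS1 was higher by 4.13 in Odoroki, from -4.70 to -0.57. In Manami it was not well above background in air and read -1.86 in propylene. Its mean difference of 2.42 (SE 1.13) did not pass limma (adjusted p = 0.791 over all probes and 0.543 over the 10 genes). With quantile normalization it was 4.69, with a limma adjusted p of 0.0314 over the 10 genes. Both values take the Manami air signal, which was not well above background, as measured, so neither their size nor that p is firm. The second PpACS1 probe was not well above background on any stony hard array and has no direction here.

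The median of all tested probes lay at 0.11 in Odoroki and -0.88 in Manami. The median of the fitted differences, each a mean of both cultivars, was -0.43, and the other genes are given relative to it. PpExp3 lay 1.64 above it, PpHexTp 1.02, PpSorTp 0.89, PpACO1 0.88, PpExp2 0.84, PpETR1 0.68 and PpERS1 0.59. These values pool a pair of bright arrays with the dim Manami air array. Among probes well above background on all 4 stony hard arrays, as those of these genes were, the median was -0.12, so the values are smaller against it. With quantile normalization the differences of PpETR1 (0.20) and PpERS1 (0.17) lay below the median of all probes (0.27). In Odoroki alone PpSorTp (-0.09), PpETR1 (-0.03) and PpERS1 (-0.18) lay below that cultivar's median of 0.11, so their positive values come from Manami. PpACO1 (0.19) and PpExp2 (0.22) lay little above that median in Odoroki. PpExp1 lay at -0.25 relative to the median of -0.43, and its unadjusted difference of -0.68 became 0.24 with normexp background correction. The 2 PpExp1 probes, which overlap in sequence, read 8.70 and 7.09 in Manami in air and 7.55 and 7.38 in propylene, so their directions differed in that cultivar. None of these 8 passed limma over all probes or over the gene-named genes.

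No probe passed limma for propylene at an adjusted p of 0.05, while 1003 of 27601 had an unadjusted p under 0.05. On simulated arrays with the spread of the real fit, this test recovered 0% of probes changed by 4 log2, so its count of 0 carries little information. By size alone, 263 probes were higher and 1831 lower by at least 2-fold in both cultivars, against 610 with opposite signs. With quantile normalization these counts were 653 higher, 923 lower and 728 opposite, and with the median of each array 898, 565 and 1074. Among the 11567 probes well above background on all 4 stony hard arrays they were 101, 572 and 50, and limma then called 28 higher and 310 lower. In Odoroki alone, whose arrays were both bright, 1186 probes were at least 2-fold higher and 2244 at least 2-fold lower. In Manami, with its dim air array, 3096 were higher and 13118 lower. With no cultivar block, limma called 0 probes without the Manami air array. With no cultivar block and without the Odoroki air array, which left the dim Manami array as the only control and assumed to vary like the others, it called 10279. With the block dropped and all 4 arrays kept it called 0. With the block kept and an intensity trend in eBayes it called 539 higher and 485 lower.

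Among probes with no gene name that read well above background on all 4 arrays, Prunus_v4_Contig4129 differed by 5.69 and Prunus_v4_Contig222 by 4.61 log2 on the mean of both cultivars. Prunus_v4_Contig3040 (probe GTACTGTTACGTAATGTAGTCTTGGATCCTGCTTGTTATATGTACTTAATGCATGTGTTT) differed by -8.84 in Odoroki and -8.77 in Manami, and Prunus_v4_Contig8707 by -4.08 and -9.41. Each is given as a value, since none passed limma.

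Akatsuki at commercial maturity was set against stony hard fruit in air, a comparison of melting fruit with fruit of the type that stays firm. The stony hard fruit had been held for 3 days after harvest, and the labels give no holding for Akatsuki. Cultivar and holding therefore cannot be told apart here. Akatsuki is the only melting cultivar, so its own traits cannot be told from those of melting fruit either. PpEndoPG read 6.74 log2 higher in Akatsuki (SE 0.69), PpExp2 5.36 (SE 0.62) and PpExp3 2.79 (SE 0.74). PpACS1 read 7.03 higher (SE 1.22), but only 1 of the 2 air arrays was well above background for it, so this value and its p partly rest on an undetected signal. Akatsuki at commercial maturity is 1 dim array, so these errors hold only the spread of the stony hard arrays, and the p-values assume that it varied likewise. On that assumption the limma adjusted p over the 10 gene-named genes was 0.00529, 0.00529, 0.0497 and 0.0155 in the same order, and none passed over all probes (adjusted p of at least 0.358). PpExp3 no longer passed over the 10 genes with quantile normalization (a difference of 1.52) or normexp (2.94). The PpExp2 difference was 3.94 with quantile normalization and 5.44 with normexp, so its size depended on the scaling, while that of PpEndoPG was 6.05 with either. PpExp2 already read 6.95 in Akatsuki at 92 days and 6.70 at 106 days, against 3.91 to 4.76 on the 4 stony hard arrays. Its higher level in Akatsuki was thus not particular to commercial maturity, though the dated arrays lay on another slide. Relative to the median of all probes, which lay at -0.36, PpExp1 differed by 2.17, PpHexTp by 1.77, PpACO1 by 1.40, PpSorTp by 1.21, PpERS1 by 0.40 and PpETR1 by -0.58, none past limma. With quantile normalization, where the median of all probes lay at 0.15, the unadjusted differences were 0.21 for PpExp1, 0.60 for PpHexTp and 0.56 for PpSorTp. The signs of the unadjusted PpACO1 and PpERS1 differences turned with that normalization.

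Limma called 0 of 27598 probes in this comparison, with 3173 at an unadjusted p under 0.05. The simulated test with the real spread recovered 0% of probes changed by 4 log2, so this count of 0 carries little information. The count with slide as a block, also 0, came from a fit that was not simulated. Slide 3 held Akatsuki at commercial maturity and both Manami samples. Within it, with 1 array on each side, Akatsuki read 6.33 higher than Manami in air for PpEndoPG, 5.24 for PpExp2 and 3.34 for PpExp3. With slide as a block these were 6.67, 5.14 and 3.15, and PpACS1 was 6.82 higher, a value that includes the Manami air signal not well above background. Without Odoroki in air, limma called 9303 probes against the dim Manami array alone, and without Manami in air it called 0.

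Against stony hard fruit in propylene, Akatsuki at commercial maturity still read higher for PpExp2, by 4.94 log2 (SE 0.62, limma adjusted p = 0.234 over all probes and 0.0144 over the 10 genes). The latter became 0.0558 with quantile normalization. PpACS1 differed by 4.61 (SE 1.22) and PpExp1 by 2.49 (SE 0.70), both with a limma adjusted p of 0.0821 over the 10 genes. PpEndoPG differed by -1.78 (SE 0.69, limma adjusted p = 0.158 over the 10 genes). Relative to the median of all probes, which lay at 0.10, PpExp3 differed by 1.47, PpHexTp by 0.71, PpACO1 by 0.49, PpSorTp by 0.29, PpERS1 by -0.21 and PpETR1 by -1.30. The unadjusted signs of PpACO1 and PpHexTp turned with quantile normalization, where PpExp1 differed by 0.62 and PpACS1 by 4.21. PpExp2 differed by 3.49 with that normalization. The sizes of the PpExp1 and PpExp2 differences thus depended on the scaling. Limma called 0 of 27598 probes, with 3409 at an unadjusted p under 0.05. Among probes well above background on all 9 arrays it called 85 higher and 88 lower. Within slide 3, against Manami in propylene, PpExp2 read 4.62 higher, PpACS1 5.25 and PpExp1 2.46, and PpEndoPG differed by -1.52. With slide as a block these were 4.72, 4.40, 2.22 and -1.86. The same assumption on the single Akatsuki array holds for these p-values. Cultivar and the 3 days of holding cannot be told apart here either.

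The Akatsuki trend probes were then followed in stony hard fruit, on arrays that share none with the trend. The 359 rising probes had a median propylene difference of 0.50 log2 in Odoroki, above all 10000 random sets of probes matched on mean signal, and the 351 falling probes had a median of -0.84, below all of them. In Manami the falling probes lay at -2.31, also below all sets, while the rising probes lay at -0.87, at percentile 80.4. Probes not well above background read higher on the dim Manami air array than in Manami propylene, which lowers the Manami medians with no change in the fruit. Among probes well above background on all 4 stony hard arrays, the 102 falling probes lay at -0.81 in Odoroki and -0.97 in Manami (percentiles 0 and 0.01), and the 135 rising probes at 0.41 and -0.35 (percentiles 100 and 76.8). On the mean of both cultivars the medians were -0.15 for rising and -1.80 for falling probes, against -0.43 for all probes, at percentiles 100 and 0. These medians moved with the scaling, to 0.48 and -0.41 with quantile normalization and 1.45 and 0.16 with the median of each array, where all probes lay at 0.27 and 1.27. On probes well above background on all 9 arrays they were 0.05 and -0.64, against -0.12 for all. Fisher's exact test of the overlap had no propylene call to work on. Probes are not independent replicates, so these percentiles describe these arrays.

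**Figure D2:**
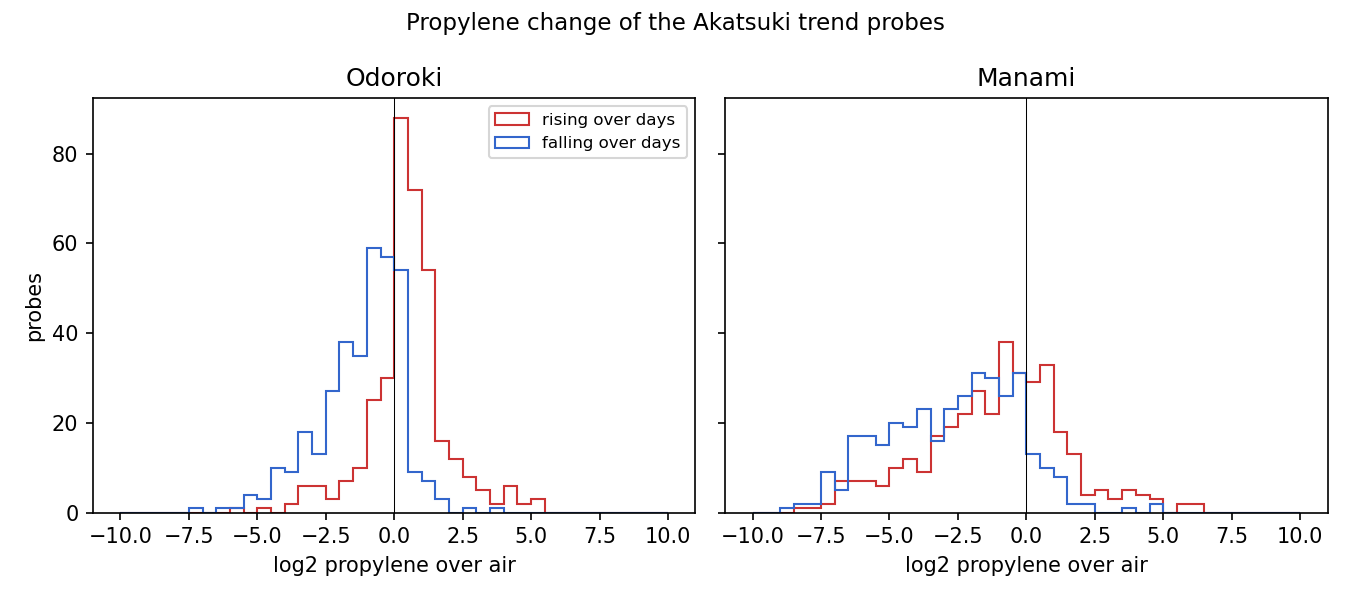
Number of probes (vertical axis) by log2 propylene over air (horizontal axis) in Odoroki and in Manami, for the probes rising and falling over days in Akatsuki. Rising probes centre on 0.50 and falling probes on -0.84 in Odoroki, and on -0.87 and -2.31 in Manami, where the air array was dim and probes not well above background read lower after propylene.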

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

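The tests in this part were chosen after the dim arrays were seen, and those of the spike-in level of each array against the other arrays and of tiles after their results were seen. Propylene differences had opposite signs in the cultivars for 3 gene-named genes and for the median of all probes, with 1 pair of arrays per cultivar, so none of these differences was tested. PpERS1 differed by -0.18 in Odoroki and 0.50 in Manami, a gap of 0.69. PpETR1 differed by -0.03 and 0.54, a gap of 0.57, but its second probe read -2.64 in air and -2.35 in propylene in Odoroki, so the opposite sign holds for 1 probe only. PpSorTp differed by -0.09 and 1.02, a gap of 1.11. The median of all tested probes lay at 0.11 in Odoroki and -0.88 in Manami, a gap of -0.99.

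The Manami air array, on which all 4 of these gaps rest, was dim. Its spike-in transcripts, added to the RNA at a fixed amount, read -2.75 log2 from their median on the other arrays, which argues against less or poorer fruit RNA as the whole cause. The 75th percentile of raw spot means lay at -3.78 log2 from the other arrays with no background subtracted, and at -4.37 less the local background, before the software's own background correction and detrending. This argues against those steps as the whole cause. Medians over 40 tiles of the surface had an SD of 0.48 on this array and at most 0.12 on the others, so uneven hybridization may contribute, and it stays open whether labelling failed too. No biological explanation for the gaps was tested apart from RNA amount.

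The array of Akatsuki at commercial maturity was dim in another way. Its spike-ins read 2.25 log2 above their median on the other arrays, which argues against poor labelling or hybridization of the whole array. The same 2.25 is what less sample RNA relative to the spike-ins needs, so that explanation stays open. A steady fall of RNA content with ripening was predicted to raise spike-ins relative to the probes from 92 to 106 days, and that value moved by -0.73. Labelling took 250 ng of RNA from each sample, so this value does not follow the RNA content of the fruit and cannot decide the question. The labels give no day for the sample at commercial maturity, and a difference between its fruit and the dated fruit is untested.

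The authors' value table did not follow the scanner values under the same probe names. Over 1622 pairs of probes that share at least 20 bases, the median r across the 9 arrays was 0.924 in the scanner files. Sequence and signal come from the same spot there, so this value does not depend on the names and cannot test them. Under the table's names it was 0.036. Table rows were joined to the sequences by name, so wrong names on either side would lower this value. A shift of the table's row names is thus a candidate explanation. Wrong names in the scanner files, on which the gene names used here rest, stay open.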

How the results depend on the processing

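Tests chosen after seeing the data were those with flagged spots kept, local medians removed, the percentile over probes well above background on all 9 arrays, slide as a block, and the filter on the 4 stony hard arrays. On the mean of both cultivars, the medians of the trend probes kept their side of the random sets under the 10 other scalings, value sources and filters run, which did not include single cultivars, left-out arrays or the intensity trend. With flagged spots kept the trend count was 645 (335 rising, 310 falling). Limma counts for propylene, 0 as reported, were 15 with the median of each array, 25 with normexp, 14 with the authors' values, 365 on probes well above background on all 9 arrays, 338 on all 4 stony hard arrays and 1024 with an intensity trend in eBayes. Leaving out a stony hard array and the cultivar block gave 0 to 10279. Trend counts, 710 as reported, were 2055 with normexp, 1690 with the authors' values, 1117 on probes well above background on all 9 arrays, 2143 with an intensity trend and 0 with 2 days against 2, and 0 to 505 without a day. With the median of each array the trend split was 381 rising and 569 falling. Commercial maturity against air, 0 as reported, gave 33 with the authors' values and 310 with an intensity trend, and 0 to 9303 without an air array. Against propylene, 0 as reported, it gave 104, 645 and, on probes well above background on all 9 arrays, 173, and 0 without either propylene array. Probes changed at least 2-fold in both cultivars, 2094 as reported, were 1007 with normexp, 649 on all 9 arrays, 673 on the 4 stony hard arrays, 4114 at 1.5-fold and 688 at 4-fold. Of 120 values of named genes under alternatives, 7 changed sign, 4 gained and 4 lost a call over the 10 genes. Gained were PpACS1 for propylene with quantile normalization (limma adjusted p = 0.0314, with a Manami air signal not well above background), PpExp1 against air with probes averaged (0.0497), and the PpHexTp slope with quantile normalization (0.0426) and normexp (0.0322). With probes averaged, PpACS1 for propylene was -0.036 and its difference from air 4.16 (limma adjusted p = 0.141), through a second probe not well above background on any array of these comparisons, so neither bears on the gene. The PpETR1 slope was then 0.0051. With quantile normalization, PpACO1 was -0.32 and PpERS1 -0.15 against air, and PpACO1 was -0.86 and PpHexTp -0.085 against propylene. With normexp, PpExp1 for propylene was 0.24. Filters changed the number of probes tested; the cause of the other moves was not tested. Gene list tests were not run, since no list had a member. Signal over background on the Manami air array limits every comparison that uses it.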

Other observations

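The tests in this part were chosen on a pattern noticed in the data, and that of the floor after the gap itself was seen. Of the 359 probes that rose over days in Akatsuki, 102 read at least 2-fold lower in Odoroki after propylene than in Akatsuki at 106 days. PpACS1 is of this kind (-0.57 against 3.59) while PpEndoPG, which just missed the trend threshold, is not (7.85 against 7.64). A hypothesis is that these probes mark a difference that both stony hard cultivars share. It was tested on arrays and a slide that took no part in the choice, as Akatsuki at commercial maturity minus Manami in propylene. The median was 2.67 log2 for the 102 probes and -0.40 for the other 257 rising probes, a gap of 3.07. Gaps lay between -0.57 and 0.68 at the 2.5th and 97.5th percentiles of 10000 shuffles of the classes. The shuffles moved single probes, not matched on signal, although some contigs have several probes among them, so their range may be too narrow. There was 1 array on each side. Part of this gap may come from the floor, since the dim array of Akatsuki at commercial maturity has the higher one and probes at background on both arrays come out positive. With both arrays raised to that floor the gap was 1.67, against -0.01 to 0.26 at the same percentiles of shuffles, so the floor does not account for all of it. At least 2-fold differences were then found for 61 of the 102 and 36 of the 257 probes. On probes well above background on both arrays the gap was 2.64 (67 and 194 probes). The gap may reflect stony hard fruit not reaching the level of Akatsuki at commercial maturity after propylene. Akatsuki, the only melting cultivar here, stands on the higher side in both the choice and the test. The gap therefore cannot tell a trait that the stony hard cultivars share from a trait of Akatsuki. Sequence differences between cultivars under a probe, or a lasting difference between cultivars unrelated to ripening, are untested and stay open. So does the 3 days of holding, which only the stony hard fruit is labelled with.

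Many probe names occurred both plain and with the prefix R_. The prefix was taken to mean the reversed orientation, which was not checked on the sequences. Of 11636 such pairs, 2619 had the plain probe and 1061 the R_ probe well above background on all 9 arrays, and 110 had both.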
